A study of Mus musculus with 4 samples.

How the data were processed

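The series profiled chromatin of mouse cortical microglia, the resident immune cells of the brain, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Per the labels' protocols, C57BL/6 mice received intraperitoneal lipopolysaccharide (LPS), a bacterial cell wall product that triggers inflammation, on 4 consecutive days. Cells carrying CD11b, a myeloid surface protein, were taken from dissociated cortex with magnetic beads. Per the labels, 2 libraries were made from material precipitated with an antibody named AceGAPDH, and 2 libraries from input chromatin. Libraries were made with a commercial ChIP-seq kit and sequenced as paired ends. All 4 samples came from LPS-treated mice, and no untreated sample was analysed here. The labels number the libraries 1 and 2 within each group and do not say whether the numbers stand for separate animals.

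The data analysed were 1 list of peaks and 1 list of their summits, both of the series as a whole. FastQC, Bowtie2 and MACS and the mouse build mm10 are named in the submitters' processing notes. Their versions, roles and parameters, and which libraries entered the peak call, are not given in the sources used here. The name of the list pairs LPS with input. It was read here as ChIP against input, and this reading could not be checked on the lists. The peak list holds the position of each peak and a score per peak, as deposited by the authors. Peak names carry the prefix MACS, and every deposited score lies above 50, which is the form in which early MACS releases write a p-value as minus 10 times its decimal logarithm. The scale is not stated in the file, so the values are reported as scores and used only to rank and describe peaks within this list. The summit list holds a whole-number pileup signal per peak, as deposited by the authors, called height below, and all summits lay inside the peak of the same name. Scores and heights are the authors' own values. Positions are given 1-based on mm10.

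Depth per library is unknown, because neither list holds read totals. Heights therefore set the precision: exact 95% Poisson intervals are given for heights and numbers of peaks, and Wilson 95% intervals for shares of peaks. Both cover counting error only, and the intervals of heights assume that a height counts independent fragments. Peaks were listed only where the signal passed the caller's limit, and the intervals of heights make no allowance for that choice. There was 1 list and no list per library, so no difference between ChIP libraries or between conditions could be tested, and no result has a replicate check. Peaks are not biological replicates. Every p-value compares this list with random positions on the genome and says nothing about variation between mice.

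Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 represents. Of 49943 genes on the 21 chromosomes, 340 that start in the first 3 Mb of a chromosome other than Y were left out, because those rows carry scaffold coordinates. This left 49603 genes, of which 21779 are protein-coding. The table gives gene starts and ends without strand, exons or sequence. The planned test of transcription start sites was therefore run on both ends of each protein-coding gene. Exon and intron shares, repeat content, GC content and motif tests were planned and not run. A peak was called intergenic when its summit lay in no protein-coding gene.

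Shares of peaks and numbers of listed genes with a peak were compared with 10000 random placements of the summits, each on the chromosome of its peak, between 3 Mb and the last gene or peak (on Y from the first gene). The test of shares was two-sided, with a smallest possible p of 0.0002, and the test of gene lists one-sided, with a smallest possible p of 0.0001. Placement did not account for assembly gaps, mappability or base composition. No peak was filtered or checked here against known regions of artefact signal, such as collapsed repeats. The number of peaks per chromosome was tested with a two-sided exact binomial test against the share of that length. Scores of peaks near gene ends and elsewhere were compared by a permutation test of the difference of medians with 100000 resamples. P-values were adjusted by the Benjamini-Hochberg method over 21 chromosomes and over 16 gene lists, with a threshold of 0.05. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

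The rule for named genes, the gene lists, the tests and most alternatives were fixed before the data were examined. The named genes are first the coding gene nearest to each of the 20 highest-scoring peaks in or within 5 kb of a coding gene. Next come the genes of the 15 highest-scoring peaks within 1 kb of a gene end. All listed genes with a peak in the gene or within 5 kb were named, as was Gapdh with its annotated pseudogenes. The rule also covers the 5 longest runs, by number of peaks, with gaps under 10 kb. Other genes were named after their values were seen, among them the genes of the highest peaks away from coding genes, those on X and Y, Zfhx3, Ftl1 and the genes found only within 20 kb. All members of the 16 lists were found in the gene table. Alternatives were stricter scores, other windows, all annotated genes, any overlap of the peak, 1 peak per run and placement over the whole genome. Tests of lists pooled together were chosen after the data were seen. They used random placement as above and 10000 draws of random coding genes, each from the 200 coding genes nearest in length to a listed gene. The count over all coding genes used 1000 placements. The tests were checked on simulated lists whose summits were all redrawn at random over the same spans as the placements. The check therefore covers the computation, and not assembly gaps, mappability or peaks that lie close together. For the share near gene ends, with 21779 genes, 33 of 1000 such lists passed the threshold. With 5% of peaks moved to gene ends, 100 of 100 lists passed. For the LPS and NF-kB list, 0 of 40 such lists passed, and 40 of 40 did so with 5 genes given a peak each. These simulated list tests used fewer than 10000 placements. No real list had more than 2 genes with a peak, and detection at that number was not simulated.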

Results

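The study asked which genomic sites nuclear GAPDH occupies in microglia of mice under stress. GAPDH is the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, which can also enter the nucleus. Chromatin of cortical microglia from LPS-treated mice was precipitated with an antibody named AceGAPDH in 2 libraries, with 2 input libraries as background. The deposited result was 1 list of 722 peaks, covering 138831 bp. Its name pairs LPS with input, and which libraries entered the call is not given in the sources used here. It holds no value per replicate.

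Most peaks were short and shallow. The median peak was 161.5 bp long (quartiles 145 and 181 bp) and its median pileup height was 8 (quartiles 7 and 9). A height of 8 has a 95% Poisson interval of 3.45 to 15.8. Heights were under 11 in 634 peaks (87.8%). Scores ranged from 50.03 to 1479.61 with a median of 56.57, and 48 peaks (6.65%) had a score of at least 100. Of the 20 highest-scoring peaks, 18 had their summit outside coding genes, as did 51.9% of the whole list; those nearest to Tmem125 and Nemf lay within 5 kb of the gene. The highest score belonged to a 4031 bp peak on chromosome 14 (19415682 to 19419712), whose nearest annotated gene was the pseudogene Gm9637 at 12265 bp. The next was a 494 bp peak in the long non-coding RNA gene Gm34259 on chromosome 17 (4626160 to 4626653), with a score of 1220.5 and a height of 39. The only coding genes that held one of these 20 summits were Ano2, a calcium-activated chloride channel gene (chromosome 6, 125876904 to 125877074, score 205.41, height 24), and Dpp9, a dipeptidyl peptidase gene (chromosome 17, 56200000 to 56200165, score 184.09, height 25). Across peaks, height and score rose together (Spearman's rho 0.53, Pearson's r of the logarithms 0.67, each with a permutation p of 0.0001, the smallest that 10000 permutations can give). Height and score come from the same peak call, so a positive relation was likely in advance and the test adds little. Peaks are not independent replicates. Whether the highest-scoring peaks, the high pileups or the runs below lie in known regions of artefact signal was not checked.

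**Figure D1:**
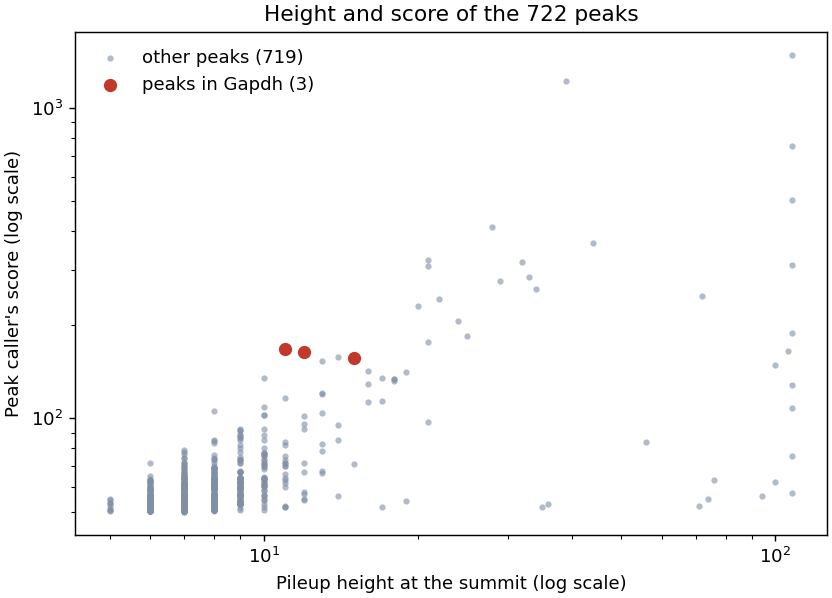
Each point is 1 of the 722 peaks, with the pileup height at the summit on the x axis and the peak caller's score on the y axis, both without units and on log scales; red points are the 3 peaks in Gapdh. Most peaks sit at heights under 11, and the 3 Gapdh peaks reach scores of 156.41 to 167.61 at heights of 11 to 15.

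Gapdh itself held 3 peaks. The gene (RefSeq gene 14433) lies on chromosome 6 from 125161852 to 125166467 and is 4616 bp long. Its peaks ran from 125161977 to 125162303 (score 156.41, height 15), from 125162356 to 125162524 (score 163.68, height 12) and from 125162664 to 125162883 (score 167.61, height 11). Their Poisson 95% intervals of height were 8.40 to 24.7, 6.20 to 21.0 and 5.49 to 19.7, and overlapped one another. The peaks spanned 907 bp, or 19.6% of the gene, all within the part at the lower coordinates, with gaps of 52 and 139 bp between them. Strand was not available, so whether that part holds the start or the end of transcription was not determined here. The 3 peaks ranked 25, 23 and 21 by score. Of 39 other peaks with heights from 11 to 15, 1, near Malt1, had a score above the lowest Gapdh score, and their median score was 71.87. Of 10000 random placements, 19 put at least 1 summit in Gapdh (one-sided permutation p = 0.0020). Random placement treats summits as independent, so it gives no chance for 3 neighbouring summits, which can be parts of 1 enriched region. Sfi1, a centrosomal protein gene of 71498 bp, and Zfhx3, a transcription factor gene of 682326 bp, were the only other coding genes with 3 peaks. None of the 3 annotated Gapdh pseudogenes had a peak within 5 kb. Mouse genomes hold further Gapdh-like copies, and how reads shared between copies were assigned is not given in the sources used here, so the height at Gapdh is uncertain to that extent.

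**Figure D2:**
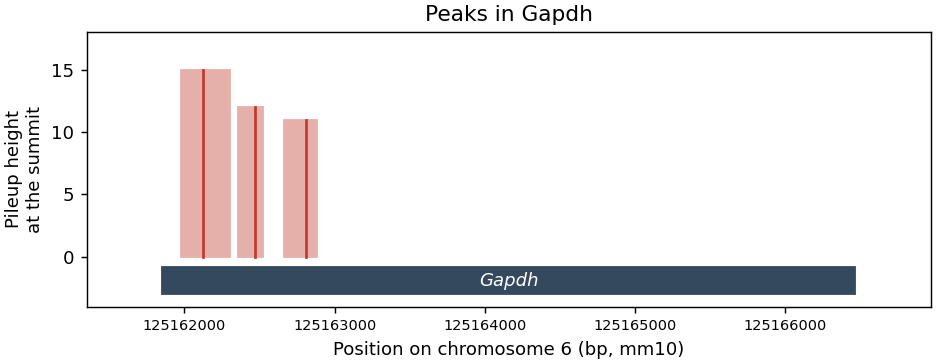
Map of Gapdh on chromosome 6 (x axis, bp, mm10) with the gene as a dark bar; each light red box is a peak drawn up to its pileup height at the summit (y axis, no unit), and the red line marks the summit. The 3 peaks, with heights of 15, 12 and 11, lie within 907 bp at the lower-coordinate end of the 4616 bp gene.

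Peaks lay near the ends of coding genes more often than random positions. Of 722 peaks, 48 had their summit within 1 kb of either end of a coding gene, which is 6.65% (Wilson 95% interval 5.05 to 8.70%), against 3.20% under random placement (95% range 1.94 to 4.57%, two-sided permutation p = 0.0002, the smallest possible). With placement within 250 kb of each summit, chosen after the data were seen, the random share rose to 4.05% (permutation p = 0.0018). The 48 peaks near gene ends are described next. The 15 highest-scoring of these peaks belonged to 13 genes. After Gapdh, they were led by Picalm, which encodes a clathrin assembly protein (chromosome 7, 90129671 to 90129848, summit 424 bp outside the gene, score 153.45, height 13, also inside the long non-coding RNA gene 2310010J17Rik). Ift172, an intraflagellar transport gene, had its summit 500 bp inside a gene end (score 105.78, height 8). Atxn3, a deubiquitinase gene, had a summit 79 bp from its end (score 92.39, height 9). Cst3, which encodes the protease inhibitor cystatin C and is highly expressed in microglia, had its summit 135 bp inside its end (chromosome 2, 148875269 to 148875425, score 73.51, height 10). Hmgb2, a chromatin protein gene, had one at 332 bp (score 66.02, height 8). The others were Rps29 (score 102.83), Gm40364 (97.47), Tmem140 (91.4), Macc1 (85.0), Stk11ip (77.9), Rusc1 (73.21) and Pla2g4e (67.86). The Rps29 peak lies at Rn7s1, a gene for the 7SL RNA of the signal recognition particle with a near-identical copy, Rn7s2, so its reads cannot be assigned with certainty. No difference in median score was found between peaks near gene ends and the other 674 (56.79 against 56.56, two-sided permutation p = 0.936). Of the 48 peaks in the whole list with scores of at least 100, 6 (12.5%) lay near a gene end, 3 of them in Gapdh.

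Coding genes contained 347 summits, 48.1% of the list, in 337 genes. The intergenic share was 51.9% (Wilson 95% interval 48.3 to 55.6%) against 58.9% under random placement (95% range 55.3 to 62.5%, two-sided permutation p = 0.0004). The difference did not pass with placement within 250 kb of each summit, chosen after the data were seen (random share 53.9%, permutation p = 0.203), or among the 362 peaks at or above the median score (54.7% against 58.5%, permutation p = 0.152). Of the 48 peaks with scores of at least 100, 66.7% were intergenic, above the random 58.4% (permutation p = 0.316).

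The 20 highest-scoring peaks in or within 5 kb of coding genes belonged to 18 genes, with scores from 102.84 to 308.62. Of these peaks, 16 lay inside the gene and 4 outside. The 4 outside lay near Nemf, a ribosome quality control gene (4244 bp away, score 308.62, height 21), near Tmem125 (3022 bp, score 247.59, height 72), near Malt1, which encodes the paracaspase of NF-kB signalling (3434 bp, score 157.55, height 14), and near Picalm. The Nemf peak is 74 bp long and lies in Rn7s2, the other 7SL RNA copy. The Tmem125 peak is 1739 bp long and lies in the long non-coding RNA gene Gm40237. Inside genes, besides Ano2, Dpp9, Gapdh and Ift172, peaks lay in Acacb, which encodes acetyl-CoA carboxylase 2 (score 142.08, height 16), in Myo7a, an unconventional myosin gene (134.95, height 17), and in Ybx3, a cold-shock domain protein gene (133.7, height 18). Lower scores were found in Zfp949, a zinc finger gene (132.21, height 18), in Npffr2, a neuropeptide FF receptor gene (120.47, height 13), and in Fam227b (119.41, height 13). Synj2, an inositol phosphatase gene, had a score of 116.34 (height 11) and Plxdc2 had 112.66 (height 16). Chl1, a neural cell adhesion gene, had a score of 108.23 at a height of 108, and Pdcd2l had 102.84 (height 10).

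Chromosomes X and Y held far fewer peaks than their length predicts, and chromosome 11 held more. X had 5 peaks (Poisson 95% interval 1.62 to 11.7) against 45.5 expected (exact binomial test, adjusted p = 3.3e-13), and Y had 4 (1.09 to 10.2) against 24.6 (adjusted p = 5.5e-06). Of the 5 on X, 1 lay inside a coding gene, Cldn34d, a claudin family gene (score 63.18, height 76). The other 4 lay nearest to Pak3 (height 108), Cldn34c1 (height 20), Btbd35f25 (height 7) and 6030498E09Rik (height 8), and those on Y nearest to Gm20865, Gm20855 and Gm21247. Chromosome 11 had 63 peaks (48.4 to 80.6) against 32.3 (exact binomial test, adjusted p = 5.5e-06) and chromosome 17 had 41 (29.4 to 55.6) against 24.9 (adjusted p = 0.0111). With the autosomes tested alone, chromosome 11 stayed past the threshold at 1.79 times its expected number (exact binomial test, adjusted p = 0.000245), and chromosome 17 did not (1.5 times, adjusted p = 0.0681). The remaining 17 chromosomes did not pass the test.

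**Figure D3:**
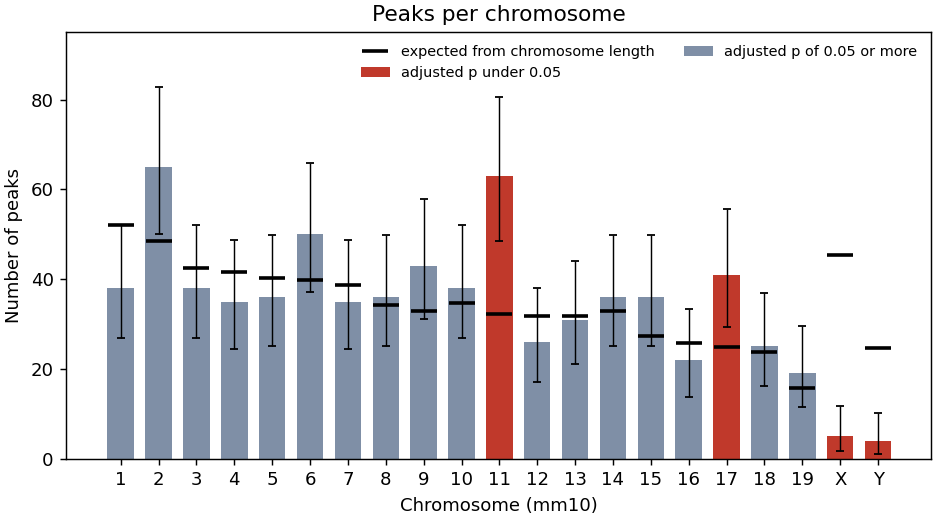
Number of peaks (y axis) on each mouse chromosome (x axis), with exact Poisson 95% intervals as error bars and the number expected from chromosome length as black dashes; red bars have an adjusted p under 0.05. X and Y, with 5 and 4 peaks, fall below 45.5 and 24.6 expected, and chromosomes 11 and 17 lie above theirs.

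Of the 249 genes in all 16 lists, 12 had a summit in the gene or within 5 kb, against 5.92 under random placement (one-sided permutation p = 0.0076) and 4.98 among random coding genes of similar length (permutation p = 0.0031). Of the 183 genes in the 10 lists for microglia, LPS and GAPDH, 9 had one, against 2.02 and 2.58 (permutation p = 0.0003 and 0.0015). Without Gapdh, 8 genes stood against 2.57 of similar length (permutation p = 0.0050). The 6 lists for other cells had 3 of 66 genes against 3.90 under random placement (permutation p = 0.802) and 2.42 among genes of similar length (permutation p = 0.440), and the difference between these groups of lists was not tested. The neuron list, with its very long genes, supplied 3.19 of the 3.90 expected and 2 of the 3 observed, and all lists but neuron had 10 of 233 genes against 2.73 under random placement (permutation p = 0.0004). The draws of genes of similar length covered 246 of the 249 genes, 182 of the 183 (181 without Gapdh) and 64 of the 66. Lists were pooled and split in this way after the data were seen, and these p-values are unadjusted. All coding genes together also exceeded random placement, with 435 genes against 353.5. No single list passed the permutation test by random placement after adjustment over 16 lists (lowest adjusted p = 0.129; 2 lists had an unadjusted p under 0.05). Among genes for nuclear partners of GAPDH, 2 of 10 had a peak against 0.163 expected (one-sided permutation p = 0.0108, adjusted p = 0.129). These were Crebbp (score 53.67, height 6) and Kat2b (score 59.93, height 8), which encode the acetyltransferases CBP and PCAF. Of 20 p53 pathway genes, 2 had a peak against 0.205 expected (permutation p = 0.0161, adjusted p = 0.129), namely Sesn1, a stress-induced sestrin gene (score 56.17, height 7), and Bax, a pro-apoptotic gene. The Bax summit lay 1360 bp outside the gene (score 50.72, height 5) and nearer to Ftl1, a ferritin gene, at 449 bp. Homeostatic microglia genes had 2 of 28, Cst3 and Sall1, a microglial transcription factor gene (score 53.41, height 6), against 0.390 expected (permutation test, adjusted p = 0.300). The LPS and NF-kB list had 1 of 34, Nfkb1 (score 56.95, height 7), against 0.316 expected (permutation test, adjusted p = 0.614). Glycolysis had 1 of 19, Gapdh (permutation test, adjusted p = 0.539), and autophagy 1 of 15, Tfeb, a lysosomal transcription factor gene (score 50.87, height 6, adjusted p = 0.539).

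No peak was listed for the 12 complement genes of the list, including C1qa, C1qb and C1qc, for the 18 interferon response genes, for the 13 antigen presentation genes or for the 14 oxidative stress genes, with 0.107, 0.130, 0.126 and 0.169 genes expected by chance. C9, a terminal complement component gene outside that list and named after its value was seen, held a peak (chromosome 15, 6451149 to 6451275, score 60.42, height 10). A count of 0 could not be told from chance for any of them, and a gene without a listed peak is not shown to be unbound. Of the lists for other cells, oligodendrocyte genes (11), endothelial and mural genes (9), genes of blood and border myeloid cells (14) and lymphocyte genes (7) had none. The astrocyte list had 1 of 9, the glutamate transporter gene Slc1a3 (score 63.66, height 9, permutation test, adjusted p = 0.539). The neuron list had 2 of 16, the very long genes Dlg2 (1973059 bp) and Lrp1b (2058309 bp), below the 3.19 expected (permutation test, adjusted p = 1). Scores of these listed genes other than Gapdh lay between 50.72 and 73.51, where the lowest score of the whole list was 50.03. Only Cst3 (73.51) and Slc1a3 (63.66) among them scored above 60, and 63.0% of the whole list scored under 60. The pooled counts therefore rest mostly on peaks not far above the lowest score listed.

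**Figure D4:**
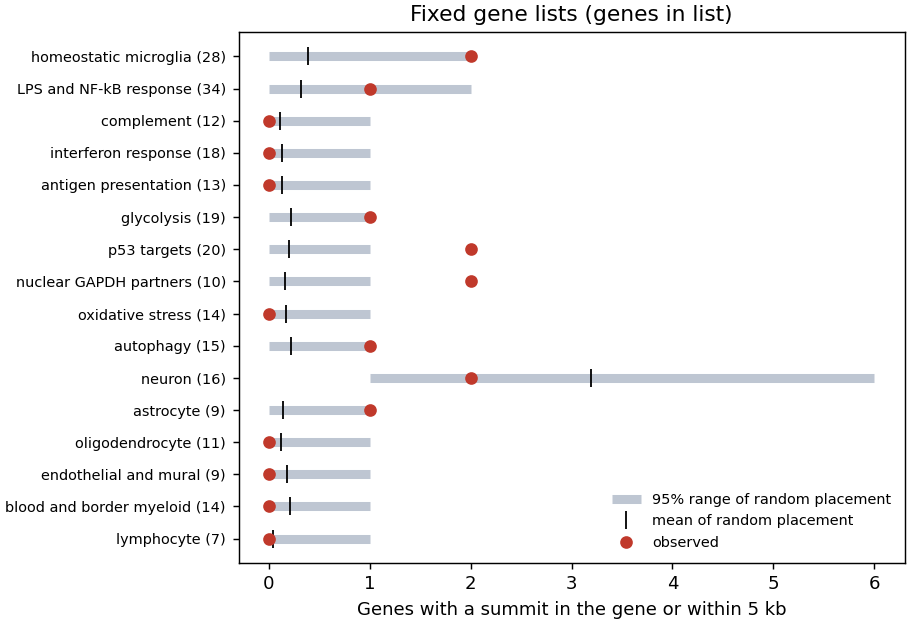
For each of 16 gene lists (y axis, number of genes in brackets), the red point gives the number of genes with a summit in the gene or within 5 kb (x axis); the grey bar is the 95% range and the black tick the mean of 10000 random placements. The p53 target and nuclear GAPDH partner lists, with 2 genes each, lie above the range of 0 to 1, and neither passed the adjusted test.

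Peaks also occurred in runs with gaps under 10 kb: 29 peaks formed 12 such runs. Runs were ranked by number of peaks, then by span. The first held 4 peaks on chromosome 2 (98662193 to 98667344), with scores from 128.09 to 751.71 and heights from 106 to 108. It spanned 5152 bp, less than the 15987 bp of the run in Sfi1. Its nearest annotated gene was the long non-coding RNA gene Gm33780. Runs of 3 lay in Sfi1 on chromosome 11 (3164372 to 3180358, heights from 35 to 56, scores from 51.89 to 83.92), in the long non-coding RNA gene 1100001I12Rik on chromosome 15 (38643703 to 38646543, heights from 7 to 12) and in Gapdh. The fifth run, of 2 peaks, lay on chromosome 6 (47763768 to 47773151) with Gm52862 and the Y RNA gene Rny3 as its nearest genes.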

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

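Placement within 250 kb, the omission of peaks of height 20 or more, the omission of the Gapdh peaks, single-copy weight for X and Y and autosomes alone were chosen after seeing the data; the other alternatives were planned. The share near gene ends stayed above random placement and past the threshold under all 10 alternatives run. The shares, 6.38 to 19.7%, come from unlike windows, peak sets and gene sets. With placement within 250 kb the share was 6.65% against 4.05% (permutation p = 0.0018), where the main random share was 3.20%. With a 5 kb window it was 19.7% against 13.1%. At scores of at least 100 it was 12.5% against 3.19% (permutation p = 0.0090), from 6 peaks of which 3 lie in Gapdh. The intergenic share stayed below random placement and past the threshold under 5 of its 8 alternatives. It was 54.7% among peaks at or above the median score (permutation p = 0.152), 51.9% against 53.9% with placement within 250 kb (p = 0.203), and 66.7% among peaks with scores of at least 100, above the random 58.4% (p = 0.316); the cause was not tested, and the last rests on 48 peaks. The list shrank from 722 to 362 and 48 peaks under these score limits, by construction. The 4 chromosomes past the threshold became 1, chromosome 11, with autosomes alone, where X and Y are left out. X and Y stayed past the threshold where they were tested; the X ratio of 0.110 became 0.046 without peaks of height 20 or more (2 peaks left), 0.175 at or above the median score and 0.209 with single-copy weight, and the Y ratio of 0.162 became 0.081 and 0.309 in the last 2. Chromosome 17 also missed it among peaks at or above the median score (exact binomial test, adjusted p = 0.215), where chromosome 2 (1.60 times expected, adjusted p = 0.0180) and chromosome 6 (1.71 times, adjusted p = 0.0133) passed. With a window of 20 kb around genes, 2 lists passed the permutation test instead of 0: astrocyte genes (3 of 9: Slc1a3, Gja1, Gfap; adjusted p = 0.0224) and glycolysis genes (3 of 19: Gapdh, Gpi1, Ldha; adjusted p = 0.0480). The peaks counted for Gfap, Gpi1 and Ldha lie inside Eftud2, Pdcd2l and Ldhc. The 2 p53 genes became 1 with the gene body only (permutation p = 0.134) and 0 at or above the median score, where the 2 partner genes became 1 (permutation p = 0.0691). At that score limit the 2 homeostatic microglia genes became 1, and the autophagy and neuron lists had 0. The LPS and NF-kB, glycolysis and astrocyte lists stayed at 1 gene each. Pooled lists are given here for the main window and all peaks only. The score difference near gene ends was 0.235, -0.295 with a 5 kb window and -0.155 with 1 peak per run, none past the threshold. Alternatives that needed sequence, exons or repeats were not run. No paired analysis was possible because the lists hold no values per library. Low heights limit comparisons between peaks: the median height of 8 has a Poisson 95% interval of 3.45 to 15.8.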

Other observations

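All tests in this part were chosen after the peak list had been seen. Beyond the fixed lists, 10 peaks lay in or within 5 kb of one of 397 zinc finger genes of the Zfp family, against 4.97 under random placement (one-sided permutation p = 0.0308, adjusted p over 5 gene families = 0.154). They included Zfp949 (score 132.21), Zfp574 (69.2), Zfp7 (64.11), Zfp993 (60.59) and the neighbours Zfp809 and Zfp599 on chromosome 9 (57.69 and 56.73). Small non-coding RNA genes had 6 peaks within 1 kb against 2.84 (permutation p = 0.0670, adjusted p = 0.167), with the 7SL RNA genes Rn7s2 (308.62) and Rn7s1 (102.83) at the top and the small nucleolar RNA gene Snord17 (56.95) among them. Long non-coding RNA genes held 72 summits against 63.9 (permutation test, adjusted p = 0.273). Pseudogenes had 13 within 1 kb against 13.6 (permutation test, adjusted p = 0.740), and olfactory and vomeronasal receptor genes had 2 within 5 kb against 6.28 (adjusted p for more peaks than chance = 0.986). None of these 5 families passed the adjusted test for more peaks than chance.

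Peaks per length and gene density were compared over the autosomes. Over 19 autosomes, observed over expected peaks and protein-coding genes per Mb had a Pearson r of 0.58 (permutation p = 0.00949) and a Spearman rho of 0.53 (permutation p = 0.0209). The relation rests in part on chromosome 11: without it r was 0.42 (permutation p = 0.0838). Chromosome 7, the most gene-dense autosome at 14.2 genes per Mb, held 35 peaks against 38.6 expected and goes against the relation. Without chromosome 7 alone r was 0.80. With 7 and 11, the farthest from the median gene density, both left out, r was 0.69 (permutation p = 0.00221). Leaving out a chromosome that goes against the relation raises r, so these values are no check of it. A preference of the signal for gene-rich regions is a hypothesis that stays open. Base composition and mappability were not tested here. Peaks also lay closer together than random positions: 28 had another summit within 10 kb, against 4.40 under random placement (95% range 0 to 10, one-sided permutation p = 0.0001, the smallest possible), where neighbouring summits can be parts of 1 enriched region.

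The first pattern to follow up is the scarcity of peaks on X and Y. A single copy of both chromosomes may contribute, as in male mice: the larger of the X and Y ratios was 0.162, lower than copy number alone gives, and a fixed threshold on shallow pileups could deepen a reduced signal. With X and Y weighted as single copies, X was still at 0.21 of its expected number (exact binomial test, adjusted p = 5.8e-05) and Y, with 4 peaks against 12.9, at 0.31 (adjusted p = 0.0375), so a loss in proportion to copy number does not cover the gap, with Y close to the threshold. Poor mappability of both chromosomes, the sex of the mice and lower occupancy on X stay open and untested.

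The second pattern is the 3 peaks in Gapdh, the gene of the protein the antibody is named for. General carry-over of abundant RNA or cDNA into the libraries stays open: 1 of 40 other genes taken to have abundant transcripts held a peak (Cst3), which is 2.5% with a Wilson upper bound of 12.9%, but abundance was not measured, and the abundant 7SL RNA genes Rn7s2 and Rn7s1, not among the 40, held peaks with scores of 308.62 and 102.83. Gapdh sequence alone, such as an amplicon or expression construct, was not tested. A construct made from cDNA would cover exons only, and exon positions were not available. An amplicon of genomic DNA need not be limited to exons. Reads shared with pseudogenes cannot be told apart from signal of the gene, because 0 of the 3 annotated pseudogenes had a peak and reads of a copy can be assigned to the gene alone. Occupancy of Gapdh by its own product, the biological hypothesis, stays open as well, as does signal of the input itself, since the libraries in the call are not given in the sources used here.

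The third pattern is very high pileups, some of them with scores that are low for their height: of 18 peaks with a height of at least 50, 11 scored below 156.41, the lowest Gapdh score at a height of 15. The 18 had a median score of 118.16, above the list median of 56.57, 10 of them scored at least 100, and 3 lay under the list median. The Gapdh scores are themselves high for their height. Of 39 other peaks with heights from 11 to 15, 1 scored above 156.41, and their median of 71.87 was below that of the 18. A candidate explanation is high signal of the input at the same places, as collapsed repeats give in many libraries. In the run on chromosome 2, 3 of the 4 peaks scored above 156.41 at heights of 106 to 108. Input heights were not analysed here, so neither these high scores nor the count of 11 tests that explanation. Of these peaks 9 shared the highest height of 108, with scores from 57.46 to 1479.61. Separate counts would seldom share a maximum in this way, so a ceiling on the pileup may have set it. Heights of 108 would then be lower bounds and not counts. Neither a ceiling nor a biological explanation was tested.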
